A study of Rattus norvegicus with 4 samples.

How the data were processed

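Neurospheres, floating clusters of cells grown from dissociated retina, were raised from embryonic day 18 Sprague Dawley rat retina under 2 conditions: medium with epidermal growth factor (EGF) alone, or EGF together with medium conditioned by endothelial cells. Total RNA was hybridized to an Affymetrix rat expression array with probe sets near the 3' ends of transcripts. Each condition had 2 arrays, labelled as biological replicates 1 and 2. Per the series description, a further pool of embryos gave the replicate of both conditions. No label ties the replicate numbers to the pools, and it was inferred that same-numbered samples share one.

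Per the labels, the authors summarised the arrays by RMA (robust multi-array average, which corrects the background and combines the probes of a probe set) in GenePattern and deposited log2 values. The RMA version and its normalization options were not given in the sources used here. The test was planned on the assumption that the deposited values had been equalised between arrays, which RMA usually does by quantile normalization. They turned out not to be: the median over all 31099 probe sets was 6.03 and 6.25 log2 in the EGF arrays and 6.84 and 6.56 log2 in the conditioned-medium arrays. The group means differed by 0.47 log2 at percentile 5, 0.79 at the lower quartile, 0.57 at the median, 0.36 at the upper quartile and 0.31 at percentile 95, so the shift was uneven.

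Probe sets were named through the platform's annotation table. Of the 31099 probe sets, 57 of them array controls, 20832 had 1 gene symbol, 436 had several and 9831 had none, and only those with 1 symbol were used for genes. Of the 20832, 20758 matched the RefSeq gene table of assembly GRCr8 by gene identifier, and no symbol needed updating. Each of the 14217 genes was represented by its brightest probe set over all 4 arrays. Genes whose probe set lay in the lowest 30% of mean values over all probe sets (under 4.77 log2) were left out, which left 11491 genes. A brighter probe set measures a change with less compression by background, and the number of arrays, not a read depth, limits the precision.

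The comparison was conditioned medium minus EGF alone, tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), without a block. On the deposited values, limma's prior swamped the 2 residual degrees of freedom, so each gene's spread came entirely from the trend with intensity. The very small adjusted p-values on that scale rest on this pooling. With median-centred arrays the prior had 10.5 degrees of freedom and with quantile normalized arrays 8.71. The main values were the deposited ones, and median centring and quantile normalization were alternatives fixed before the data were examined. Because the scaling moved the split of calls, the words rose and fell are used only of genes past the threshold in the same direction under all 3 scalings. That rule was chosen after seeing the data. Effect sizes are quantile normalized log2 differences with limma's standard error unless they are called deposited.

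The pairing was checked through the correlation, across genes, of the deviations of same-numbered arrays from their group means. It was -0.12 on deposited and -0.03 on quantile normalized values, over only 2 pairs, so a count that drops under the block is not shown to drop because of shared embryos. Values with the replicate as a block are given where they change a call or move a count by more than 1.5 times.

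Gene lists for retinal cell types, signalling, proliferation, stress and other cell types the cultures could hold were fixed before the data were examined, 31 in all. The 30 lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over the 30 lists. Counts of members are given over all genes tested and adjusted over the list alone. They are out of tested members only. Too dim to be tested were 9 of 18 endothelial, 7 of 14 lens, 5 of 19 mesenchymal and 3 of 16 microglia markers on the array. The filter used the mean over all 4 arrays, so a dim gene passed more easily if it was high in 1 condition. The genes to name were also fixed by rule: per direction, the 12 largest log2 differences among genes past the threshold whose groups did not overlap, up to 4 members per list with the smallest p, and Hmga2 and Lin28b in any case. Differences and p-values for this rule were those of the deposited values. Symbols that are only predicted were passed over. Genes named beyond this rule (Elavl4, Otx2, Thrb, Gnat1, Pax6, Rax, Sox2, Nusap1, Slc1a2, Ndrg1, the genes of the added lists and those of the tests of explanations) were chosen after their values were seen. A further 8 lists were chosen after seeing the data and were adjusted over those 8 alone.

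The procedure was tested on simulated data with the 11491 genes of this comparison. The simulated genes varied independently around quantile normalized means, with no shift between arrays, and the rule over all 3 scalings was not applied. The procedure recovered 84% of 100 genes changed by 1 log2 and 99% of 100 genes changed by 2 log2, and 2.66% of its calls were false. These rates therefore do not carry over to the calls on the deposited values or under all 3 scalings. It found the 1 list shifted by 0.7 log2 and called 0 of the others, but with an estimated correlation the shifted list was not found (adjusted p = 0.167).

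Alternatives covered the scaling of the arrays, the replicate block, the filter on dim probe sets, the choice of probe set per gene, the intensity trend and robust fit, a fold-change threshold, each array left out in turn, and the list test (an estimated correlation, or fry). The 9 hybridization control probe sets were used for 1 further scaling. No coordinates are given because the array table names no genome build.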

Results

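Expression was measured in 4 arrays of rat retinal neurospheres, 2 grown with EGF alone and 2 grown with EGF and medium conditioned by endothelial cells, the cells that line blood vessels. The array medians were 6.03 and 6.25 log2 with EGF alone and 6.84 and 6.56 log2 with conditioned medium. Arrays of the same condition differed across genes by an SD of 0.27 log2 (EGF) and 0.21 log2 (conditioned medium), against 0.47 to 0.52 log2 for the 4 pairs of arrays from different conditions. The mean between conditions was 2.04 times that within conditions, and 2.00 times after quantile normalization. The gap between the 3' and 5' control probe sets of actin, which widens as RNA is degraded, was 1.99 and 2.08 log2 with EGF alone and 1.54 and 1.37 log2 with conditioned medium. This gap therefore moved with the condition in every comparison that follows.

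**Figure D1:**
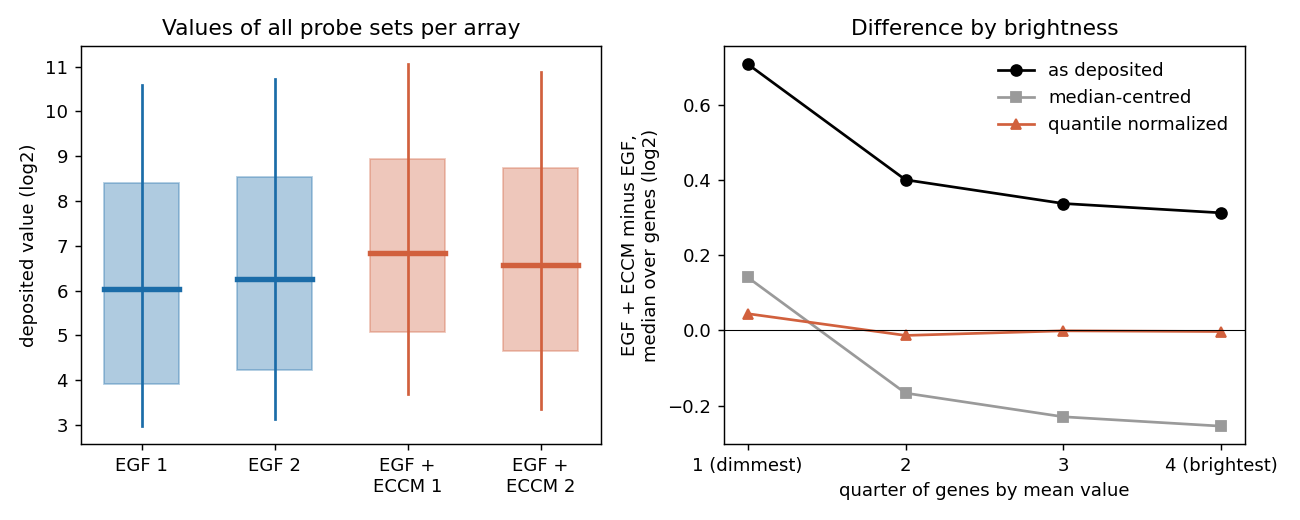
Left, the deposited log2 values of all probe sets in each of the 4 arrays (bar, median; box, quartiles; line, percentiles 5 to 95), where the conditioned-medium arrays (EGF + ECCM) have medians of 6.84 and 6.56 log2 and the EGF arrays 6.03 and 6.25 log2. Right, the median log2 difference of the tested genes in 4 equal groups by mean value under the 3 scalings, which goes from 0.71 log2 in the dimmest to 0.31 log2 in the brightest group as deposited and runs from 0.04 to 0.00 log2 when quantile normalized.

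The comparison asks which genes endothelial conditioned medium changes in retinal neurospheres that already receive EGF. With conditioned medium Upk1b, Ets1 and Anxa1 rose most, and 15 of 23 genes of extracellular matrix and adhesion rose, together with 20 of 21 genes of mitosis, 10 of 20 of the MAP kinase response and 9 of 16 of the retinal progenitor state. Of 17 photoreceptor genes 12 fell, led by the short-wave cone opsin Opn1sw. These 5 lists were called in camera at a preset correlation but not at an estimated one (adjusted p = 0.629 to 0.646). The estimated setting also missed the shifted list in the simulated data. In the deposited values 4643 of 11491 genes were higher and 205 lower (limma, adjusted p under 0.05), so 95.8% of calls were higher. That share was 24.1% with median-centred arrays (1176 higher, 3704 lower) and 53.1% with quantile normalized arrays (1890 higher, 1672 lower), and the median difference of all genes was 0.40, -0.16 and 0.00 log2 in turn. Past the threshold in the same direction under all 3 scalings were 1048 higher and 205 lower genes, of which 260 and 81 differed by at least 1 log2 and 28 and 3 by at least 2 log2. The deposited values lay higher with conditioned medium and limited the falls (205 lower), and median centring limited the rises (1176 higher). By the fold alone, 1314 genes were higher and 18 lower by at least 1 log2 as deposited with no overlap of the groups, against 261 and 123 after quantile normalization.

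The counts moved when single arrays were left out and when the replicate was a block. Under all 3 scalings, 904 genes were higher and 72 lower without EGF replicate 1, 707 and 43 without EGF replicate 2, 630 and 104 without conditioned-medium replicate 1, and 549 and 58 without conditioned-medium replicate 2. With the replicate as a block, the deposited values gave 1280 higher and 28 lower genes, and all 3 scalings together gave 1026 and 28.

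Upk1b, a uroplakin family membrane protein, rose most, from 4.44 ± 0.13 to 9.06 ± 0.16 log2 as deposited (SD, n = 2 per group), which was 16.4-fold after quantile normalization (log2 difference 4.04 ± 0.19 SE, limma adjusted p = 2.50e-07). Ets1, a transcription factor active in endothelial cells among others, rose 9.95-fold (3.32 ± 0.18 SE), and Anxa1, a phospholipid-binding annexin, rose 9.43-fold (3.24 ± 0.17 SE). Col1a2, a chain of type I collagen, rose 7.75-fold, from 6.68 ± 0.20 to 10.05 ± 0.08 log2 as deposited (SD, n = 2 per group). Genes of the actin cytoskeleton and muscle rose beside it, namely the calponin Cnn2 (2.79 log2), transgelin Tagln (2.69 log2) and cardiac troponin T, Tnnt2 (2.51 log2). The remaining genes among the 12 with the largest rise as deposited were the co-chaperone Bag3 (2.87 log2), the RNA-binding protein Cpeb1 (2.80 log2), the membrane-repair protein Myof (2.77 log2), the leukocyte sialoglycoprotein Spn (2.61 log2) and the syntaxin Stx11 (2.50 log2). Of the 12 genes, 9 had an EGF mean under the 4.77 log2 limit for dim probe sets, so the sizes of those rises are less certain than their direction. All 12 stayed past the threshold under all 3 scalings when any of the 4 arrays was left out and with the replicate as a block.

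Opn1sw, the opsin of short-wave cones, fell most, from 10.19 ± 0.08 to 8.14 ± 0.06 log2 as deposited (SD, n = 2 per group), a 5.32-fold fall after quantile normalization (-2.41 ± 0.09 SE, limma adjusted p = 1.31e-07). Cnga1, a subunit of the rod cyclic nucleotide-gated channel, fell 5.22-fold (-2.38 ± 0.27 SE), and Pdc, the phototransduction regulator phosducin, fell 4.20-fold (-2.07 ± 0.08 SE). The photoreceptor cadherin Cdhr1 (-1.68 log2) and the outer-segment disc protein Rom1 (-1.45 log2) fell too. Among genes of other retinal neurons, the LIM homeobox factor Lhx9 fell by 1.64 log2 and the neuropeptide Sst, somatostatin, by 1.69 log2. Ccdc136 (-1.91 log2), Marchf1 (-1.83 log2), Efhc2 (-1.81 log2), Wdr17 (-1.77 log2) and Rtn4rl2 (-1.58 log2) complete the 12 largest falls, ranked by the deposited difference. Cnga1 and Efhc2 had conditioned-medium means of 4.34 and 4.52 log2, under the 4.77 log2 limit for dim probe sets, so the sizes of these falls are less certain than their direction. Efhc2 was lost under all 3 scalings with the replicate as a block and with any 1 of the 4 arrays left out, and Cnga1 was lost without EGF replicate 2.

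**Figure D2:**
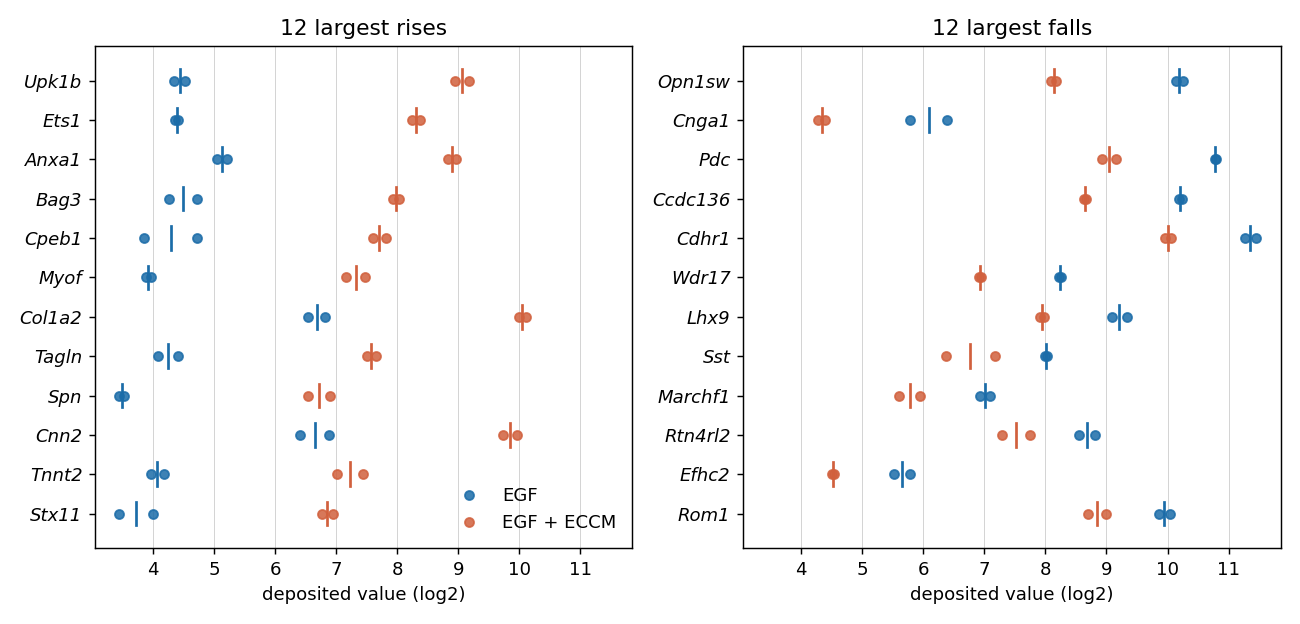
Deposited log2 values of the 12 genes with the largest rise and the 12 with the largest fall by the deposited difference, 1 point per array and a vertical line at the mean of each group (blue, EGF, and orange, conditioned medium). Upk1b goes from a mean of 4.44 to 9.06 log2 and Opn1sw from 10.19 to 8.14 log2 with conditioned medium.

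Of the 30 gene lists tested, 16 shifted against the other genes (camera at a preset correlation), 12 higher and 4 lower, and 14 of them did so under all 3 scalings. With an estimated correlation 0 lists passed in camera and 0 had an unadjusted p under 0.05, and fry called 0 (15 at an unadjusted p under 0.05, lowest adjusted p = 0.0633). The lowest adjusted p with an estimated correlation was 0.629 on deposited and 0.184 on quantile normalized values.

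Of 17 photoreceptor markers tested, 12 fell and 0 rose, both over all genes and adjusted over the list alone, with a median of -1.22 log2 (-0.85 log2 as deposited). The list was lower in camera (adjusted p = 4.19e-35), with adjusted p = 0.629 with an estimated correlation. Besides Opn1sw, Pdc and Rom1, the rod arrestin Sag fell by 1.43 log2. Otx2, the homeobox factor that starts the photoreceptor lineage, did not pass under all 3 scalings (-0.35 ± 0.08 SE), nor did the thyroid hormone receptor Thrb (-0.38 ± 0.10 SE). The rod transducin Gnat1 differed by 0.00 ± 0.30 log2 (SE). The EGF mean of Gnat1, 4.58 log2 as deposited, lies under the limit for dim probe sets, so its difference cannot show whether it fell. Without EGF replicate 2 the count was 10, with any other array left out 11, and with the replicate as a block 10. In the same arrays the actin gap differed by -0.58 log2 and 8 of 13 microglia, 9 of 14 mesenchymal and 3 of 7 lens markers rose.

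Among 13 proneural and early neuronal genes 3 fell, the transcription factor Bhlhe22 (-0.86 log2), the neuronal tubulin Tubb3 (-0.75 log2) and the RNA-binding protein Elavl4 (-0.80 log2), while Sox11, a factor of immature neurons, rose by 0.88 log2. Among 19 amacrine and horizontal cell markers 3 fell and 0 rose, namely the calcium-binding protein Calb2 (-1.07 log2), the GABA-synthesizing enzyme Gad1 (-0.83 log2) and the homeobox factor Meis2 (-0.71 log2). Among 9 bipolar cell markers, Pcp2 fell (-1.23 log2). Adjusted over the list alone, the counts of these 3 lists were the same. The lists were lower in camera (adjusted p = 6.17e-04 for the proneural, 2.08e-05 for the amacrine and horizontal and 8.50e-03 for the bipolar list), each with adjusted p = 0.646 with an estimated correlation, and the bipolar list had adjusted p = 0.101 with median-centred arrays and 0.0875 without EGF replicate 1. The falls of the proneural and of the amacrine and horizontal markers dropped to 0 with the replicate as a block. Without EGF replicate 1, EGF replicate 2, conditioned-medium replicate 1 and conditioned-medium replicate 2, the falling proneural genes numbered 0, 0, 1 and 0 and the falling amacrine and horizontal markers 1, 0, 2 and 0. The mean of all Tubb3 probe sets differed by 0.27 log2 as deposited, against -0.43 log2 for its brightest probe set. In the same arrays 8 of 13 microglia and 9 of 14 mesenchymal markers rose. Of 12 retinal ganglion cell markers, Rbpms rose (1.33 log2, and 0.79 log2 for its other probe set) and 0 fell, also adjusted over the list alone, and the list had camera adjusted p = 0.0724 as deposited and 0.0153 after quantile normalization, with adjusted p = 0.872 and 0.263 with an estimated correlation. After quantile normalization alone, 7 ganglion cell, 9 proneural, 11 amacrine and horizontal and 6 bipolar markers were lower. Higher on that scale were 1, 2, 0 and 0 of them in turn.

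Retinal progenitor factors rose in 9 of 16 tested and fell in 0, and the same counts held adjusted over the list alone. After quantile normalization alone, 10 were higher and 3 lower, and the lowest difference was -0.56 log2, so the list did not move as 1. Id3 and Id1, inhibitors of basic helix-loop-helix factors, rose by 2.45 ± 0.09 and 1.74 ± 0.10 log2 (SE), the growth factor Fgf19 by 2.02 ± 0.19 log2 and cyclin D1, Ccnd1, by 1.35 ± 0.08 log2. The eye-field factors Pax6 (-0.15 ± 0.06 SE) and Rax (-0.24 ± 0.07 SE) and the stem cell factor Sox2 (0.07 ± 0.07 SE) did not pass under all 3 scalings. The list was higher in camera (adjusted p = 7.49e-12), with adjusted p = 0.629 with an estimated correlation. In the same arrays 8 of 13 microglia and 9 of 14 mesenchymal markers rose.

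Of 21 mitosis genes 20 rose, and 21 adjusted over the list alone, with a median of 0.75 log2. The aurora kinases Aurkb (1.03 ± 0.08 SE) and Aurka (0.99 ± 0.10 SE), the ubiquitin-conjugating enzyme Ube2c (0.92 ± 0.17 SE) and cyclin B, Ccnb2 (0.90 ± 0.08 SE) were among them, and Nusap1 (0.52 ± 0.08 SE) did not pass under all 3 scalings. Among 19 DNA replication genes 7 rose and 0 fell, also adjusted over the list alone, including Gins1 (0.81 log2), the helicase subunit Mcm5 (0.73 log2) and the S phase transcription factor E2f1 (0.62 log2), and Fen1 (0.66 ± 0.20 SE) did not pass. Ube2c was lost without EGF replicate 2, conditioned-medium replicate 1 or conditioned-medium replicate 2. Without EGF replicate 2 the replication count was 4 and without conditioned-medium replicate 2 it was 3. Both lists were higher in camera (adjusted p = 1.09e-18 for mitosis and 1.06e-05 for replication), with adjusted p = 0.629 and 0.646 with an estimated correlation. In the same arrays 8 of 13 microglia and 9 of 14 mesenchymal markers rose. Among 15 cell cycle inhibitors and p53 targets only the inhibitor Cdkn1c rose (1.03 ± 0.08 SE), also adjusted over the list alone (camera adjusted p = 0.177).

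Hmga2, a chromatin protein of fetal stem cells, had a probe set too dim to be tested, at 4.25 log2 with EGF and 5.07 log2 with conditioned medium as deposited, and its difference was 0.01 log2 after quantile normalization. Lin28b had no probe set with a single gene name here. Among 12 tested genes of self-renewal and the let-7 and Hmga2 axis, the drug efflux transporter Abcg2 alone rose (0.50 ± 0.16 SE), and 0 passed adjusted over the list alone. Abcg2 was lost with the replicate as a block and with any 1 of the 4 arrays left out. Myc (0.38 ± 0.13 SE) and the RNA-binding proteins Igf2bp2 (0.37 ± 0.10 SE, and -0.11 log2 for its other probe set) and Igf2bp1 (0.36 ± 0.14 SE) did not pass under all 3 scalings, and the list did not shift (camera adjusted p = 0.843).

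Of 20 genes of the MAP kinase response 10 rose and 0 fell, and 12 rose adjusted over the list alone. Egr2 (1.74 ± 0.10 SE) and Egr1 (0.98 ± 0.07 SE), zinc finger factors induced within minutes of stimulation, the feedback inhibitor Spry1 (1.45 ± 0.15 SE) and the ETS factor Etv1 (1.40 ± 0.08 SE, the highest of 5 probe sets that start at 0.80 log2) were among them. Of 15 Wnt pathway genes 6 rose, also adjusted over the list alone, including the nuclear effectors Tcf7l2 (1.11 log2, the highest of 4 probe sets that start at 0.15 log2) and Lef1 (1.09 log2), the secreted antagonist Sfrp1 (0.89 log2) and the receptor Fzd2 (0.66 log2). Of 18 genes of TGF-beta and BMP signalling 6 rose, and 7 rose and 1 fell adjusted over the list alone. Id3, Id1 and Id2 (1.14 log2), which BMP signals induce, and the ligand Bmp2 (0.60 log2) were among them (Id1 and Id3 are also on the progenitor list), and the count was 3 without conditioned-medium replicate 2. The MAP kinase, Wnt and TGF-beta lists were higher in camera (adjusted p = 3.13e-11, 2.24e-03 and 1.21e-03), each with adjusted p = 0.646 with an estimated correlation. The Wnt count was 4 without conditioned-medium replicate 1 and without conditioned-medium replicate 2. Fzd2 was lost without the former and Bmp2 without the latter. Beside these genes, 8 of 13 microglia and 9 of 14 mesenchymal markers rose.

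Other signalling lists were not called in camera on deposited values. Of 17 Notch genes 2 rose, the Notch targets Hes1 (0.64 ± 0.12 SE) and Hey1 (0.55 ± 0.08 SE), and 1 adjusted over the list alone (camera adjusted p = 0.279). Hey1 was lost with the replicate as a block, and the Notch count was 0 without EGF replicate 2 and 1 with any other array left out, where Hey1 was lost without conditioned-medium replicate 2 and Hes1 otherwise. Of 7 hedgehog genes the transducer Smo rose (0.56 ± 0.10 SE), also adjusted over the list alone (camera adjusted p = 0.638), and the count was 0 without EGF replicate 1, conditioned-medium replicate 1 or conditioned-medium replicate 2. Of 19 angiogenic and growth factor genes 4 rose, also adjusted over the list alone, among them the growth factors Igf2 (1.19 ± 0.10 SE, the highest of 3 probe sets that start at 0.22 log2) and Vegfc (0.77 ± 0.15 SE) and the receptor Fgfr1 (0.51 ± 0.10 SE). Without EGF replicate 1, EGF replicate 2, conditioned-medium replicate 1 and conditioned-medium replicate 2 that count was 2, 2, 1 and 1. Fgfr1 was lost with the replicate as a block and with any 1 of the 4 arrays left out, and Vegfc without either conditioned-medium array. This list had camera adjusted p = 0.0724 as deposited and 4.15e-03 with median-centred arrays, with adjusted p = 0.842 with an estimated correlation on deposited values.

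Extracellular matrix and adhesion genes rose in 15 of 23 tested and fell in 0, also adjusted over the list alone. Examples are the collagen Col5a2 (2.12 ± 0.09 SE), the matricellular proteins Ccn2 (1.80 ± 0.09 SE) and Sparc (1.14 ± 0.06 SE) and the integrin Itgb1 (0.99 ± 0.08 SE). Of 14 tested markers of pericytes, fibroblasts and other mesenchymal cells 9 rose, and 10 adjusted over the list alone. A further 5 on the array were too dim to be tested. Besides Col1a2 and Tagln these included the transcription factor Twist1 (1.36 ± 0.21 SE, from a dim EGF mean of 4.70 log2 as deposited) and fibronectin, Fn1 (1.08 ± 0.17 SE). Both lists were higher in camera (adjusted p = 7.49e-12 for matrix and 4.51e-09 for mesenchymal), each with adjusted p = 0.629 with an estimated correlation. Without EGF replicate 1, EGF replicate 2, conditioned-medium replicate 1 and conditioned-medium replicate 2, the matrix count was 10, 11, 11 and 7 and the mesenchymal count 6, 4, 3 and 4. Fn1 was lost without conditioned-medium replicate 1. Of 13 microglia markers 8 rose in the same arrays.

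Of 16 Müller glia markers 6 rose, and 7 adjusted over the list alone, including clusterin, Clu (1.86 ± 0.06 SE, and 0.02 log2 for its other probe set), the calcium-binding S100a16 (1.32 ± 0.10 SE), the intermediate filament vimentin, Vim (0.99 ± 0.11 SE), and the glutamate transporter Slc1a3 (0.65 ± 0.08 SE), whose 3 probe sets ran from -0.65 to 0.71 log2. The Müller list was higher in camera on deposited values (adjusted p = 1.21e-03), with adjusted p = 0.646 with an estimated correlation, and not with median-centred (adjusted p = 0.133) or quantile normalized arrays (adjusted p = 0.103). The Müller count was 4 without EGF replicate 2, where Slc1a3 was lost, and 3 without conditioned-medium replicate 2, where Slc1a3 and Vim were lost. Of 11 astrocyte markers the receptor Fgfr3 (1.11 ± 0.13 SE) and the connexin Gja1 (0.75 ± 0.08 SE) rose and the glutamate transporter Slc1a2 fell (-1.03 ± 0.13 SE), with 2 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.907). A second probe set of Gja1 stood at -0.13 log2. The fall of Slc1a2 was lost with the replicate as a block and with any 1 of the 4 arrays left out. Of 7 oligodendrocyte lineage markers only the receptor Pdgfra rose (0.62 ± 0.18 SE), also adjusted over the list alone (camera adjusted p = 0.640), and it was lost with any 1 of the 4 arrays left out. Microglia markers rose in 8 of 13 and mesenchymal markers in 9 of 14 in the same arrays.

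Of 13 microglia and macrophage markers 8 rose, and 10 adjusted over the list alone, among them the adaptor Tyrobp (1.16 ± 0.17 SE), the receptor subunit Fcer1g (1.08 ± 0.11 SE) and the growth factor receptor Csf1r (1.01 ± 0.20 SE), with Laptm5 at 0.77 ± 0.13 log2 (SE). Of 9 endothelial markers 3 rose, and 4 adjusted over the list alone: Ets1, the vascular growth factor receptor Flt1 (2.09 ± 0.29 SE, EGF mean of 3.49 log2 as deposited) and the adhesion protein Esam (0.72 ± 0.20 SE). The receptor Kdr did not pass under all 3 scalings (0.41 ± 0.06 SE, and -0.14 log2 for its other probe set). Of 7 lens markers 3 rose, and 4 adjusted over the list alone, the crystallins Crybb3 (1.53 ± 0.12 SE), Crybb1 (0.93 ± 0.29 SE, EGF mean of 4.72 log2) and Cryab (0.84 ± 0.16 SE). The EGF means of Flt1, Ets1 and Crybb1 lie under the limit for dim probe sets, so the sizes of these rises are less certain than their direction. A further 3 microglia, 9 endothelial and 7 lens markers on the array were too dim to be tested. The shares that rose are therefore of tested markers only, and a dim marker passed the filter more easily if it was high in 1 condition. The microglia, endothelial and lens lists were higher in camera (adjusted p = 1.87e-04, 1.21e-03 and 8.50e-03), each with adjusted p = 0.646 with an estimated correlation. Without EGF replicate 1, EGF replicate 2, conditioned-medium replicate 1 and conditioned-medium replicate 2, the microglia count was 6, 6, 5 and 3, the endothelial count 3, 2, 2 and 2 and the lens count 1, 2, 2 and 1. Crybb1 was lost with any 1 of the 4 arrays left out, Cryab without EGF replicate 1 or conditioned-medium replicate 2, Csf1r without conditioned-medium replicate 2, and Esam with any array except EGF replicate 1 left out. Of 8 pigment epithelium and ciliary margin markers, the melanocyte factor Mitf (0.65 ± 0.16 SE) and Gja1 rose, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.905). Mitf was lost with any 1 of the 4 arrays left out. The 4 tested erythroid markers gave 0 calls under all 3 scalings and were too few for the list test.

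Metabolic and stress lists were not called in camera on deposited values. Of 24 genes of the amino acid and ER stress response 5 rose, also adjusted over the list alone (camera adjusted p = 0.168), including the transcription factor Cebpb (1.10 ± 0.14 SE), the amino acid transporter Slc7a5 (0.73 ± 0.07 SE) with its partner Slc3a2 (0.52 ± 0.06 SE), and the serine synthesis enzyme Phgdh (0.62 ± 0.09 SE). Without EGF replicate 1, EGF replicate 2, conditioned-medium replicate 1 and conditioned-medium replicate 2 that count was 3, 3, 2 and 2. Slc3a2 was lost with the replicate as a block and with any 1 of the 4 arrays left out, and Phgdh with any array except EGF replicate 1 left out. Of 12 oxidative stress genes heme oxygenase, Hmox1 (1.20 ± 0.13 SE), and the quinone reductase Nqo1 (0.54 ± 0.13 SE) rose, also adjusted over the list alone (camera adjusted p = 0.123), and Nqo1 was lost with any 1 of the 4 arrays left out. Of 18 glycolysis and hypoxia genes the peptide hormone Adm (0.92 ± 0.26 SE, from a dim EGF mean of 4.30 log2 as deposited, which leaves the size uncertain) and the glycolytic enzyme Pfkp (0.70 ± 0.08 SE) rose and Ndrg1 fell (-0.75 ± 0.10 SE), also adjusted over the list alone (camera adjusted p = 0.843). Ndrg1 was lost with the replicate as a block, and both Ndrg1 and Adm were lost with any 1 of the 4 arrays left out. After quantile normalization the glycolysis list had a median of 0.02 and a mean of 0.05 log2 while camera put it lower. Of 14 interferon and inflammatory genes Ifit1 rose (1.04 ± 0.29 SE, likewise from a dim EGF mean, 3.99 log2), also adjusted over the list alone (camera adjusted p = 0.542), and it was lost with any 1 of the 4 arrays left out. Of 18 cholesterol synthesis genes 0 passed under all 3 scalings or adjusted over the list alone, 3 were higher as deposited, and camera gave adjusted p = 0.765. The cholesterol list had a median of 0.00 and a mean of -0.02 log2 after quantile normalization.

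**Figure D3:**
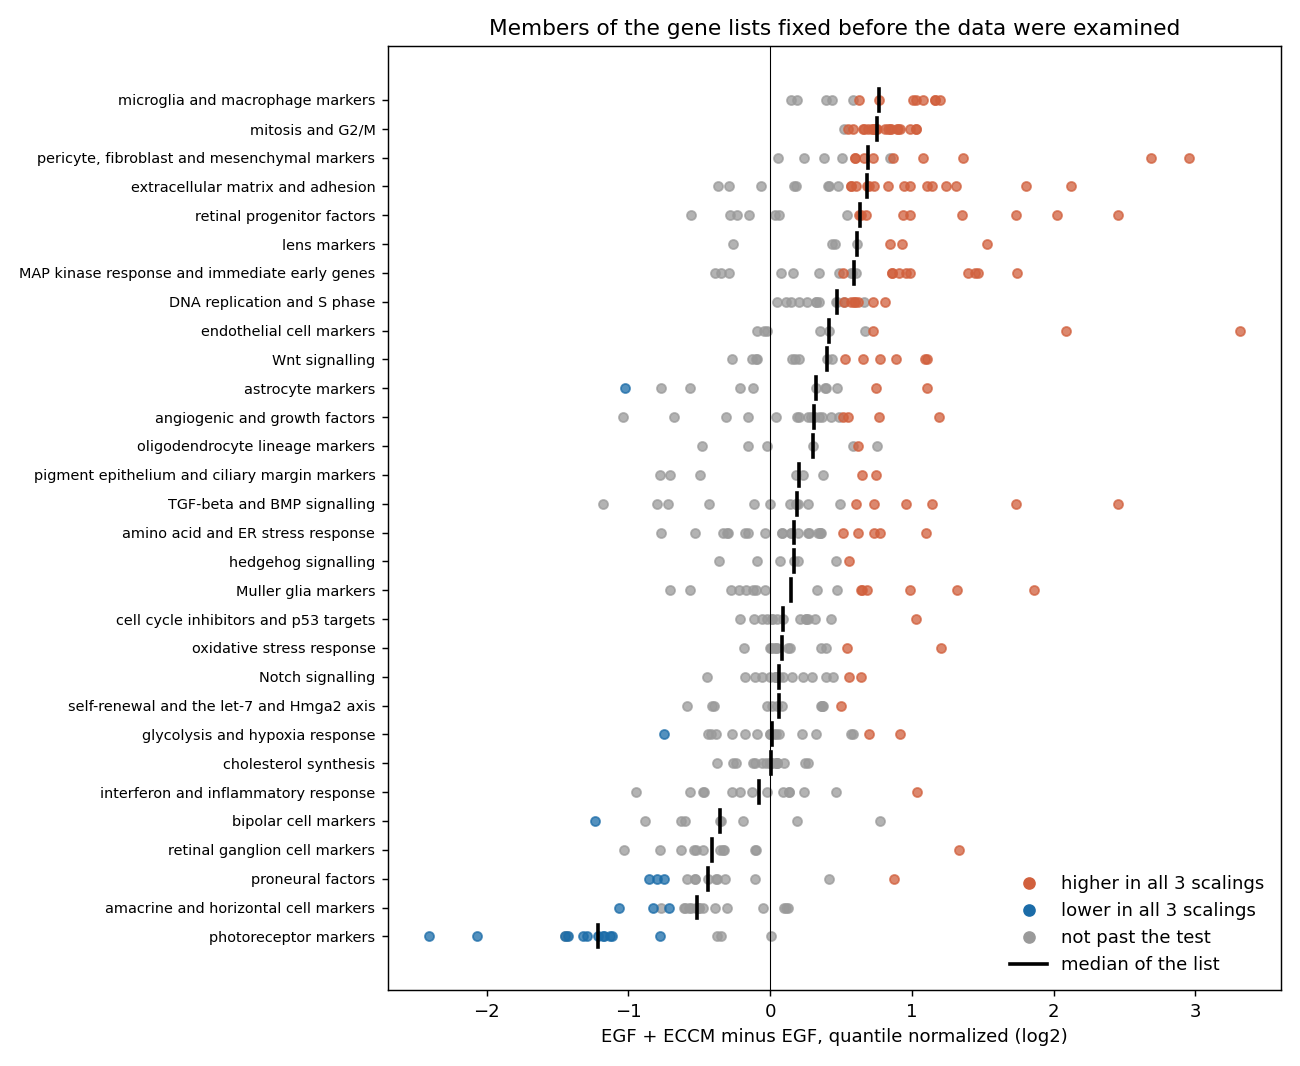
Quantile normalized log2 differences, conditioned medium minus EGF, of the tested members of each gene list (1 point per gene, coloured by its calls under the 3 scalings, with a bar at the median of the list). The photoreceptor list has the lowest median, -1.22 log2, and the microglia and mitosis lists stand at 0.77 and 0.75 log2.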

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

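Probe sets that carry no gene name or several names entered none of the comparisons above, yet many of them differed between the conditions. Of 5712 such probe sets above the limit for dim signals, 289 were higher and 77 lower with conditioned medium under all 3 scalings (limma, adjusted p under 0.05), against 1048 higher and 205 lower of 11491 named genes. They drew attention because they form a signal in data outside the named genes, and their genes were not analysed here.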

How the results depend on the processing

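The deposited values gave 4643 higher and 205 lower genes. Alternatives from the hybridization controls, the rule over all 3 scalings, the crossed pairing and the combinations with quantile normalization were chosen after seeing the data. The scaling moved the counts most: 1176 higher and 3704 lower with median-centred arrays, 1890 and 1672 quantile normalized, 5302 and 507 with the hybridization controls made equal, and 1048 higher under all 3 scalings. The median-centred and quantile results follow from removing the shift between arrays. With the replicate block the counts were 1280 and 28, and quantile normalized with the replicate block 1823 and 1570. Beyond the calls and counts given with the results, the block changed no call of a gene list or, under all 3 scalings, of a named gene. Because the deviations of same-numbered arrays correlated below -0.1, the crossed pairing was also run and gave 7651 higher and 441 lower genes. Without the intensity trend 133 genes were lower, every probe set on its own gave 8324 and 328, and a fold of at least 1 log2 besides the adjusted p gave 1293 and 18. Leaving out each array in turn gave 1328 to 3993 higher and 44 to 105 lower genes, where the lone array of a group is assumed to vary like the other group. Quantile normalized and without EGF replicate 1, EGF replicate 2, conditioned-medium replicate 1 or conditioned-medium replicate 2 in turn, 1175, 1028, 803 and 828 genes were higher and 852, 731, 707 and 770 lower. Apart from the scalings, the filters and the arrays left out, the cause of these moves was not tested.

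By the fold alone (1314 higher, 18 lower), the counts were 632 higher with the dimmest 50% left out, 242 and 216 median-centred, 261 and 123 quantile normalized, 3533 and 98 at 1.5-fold, 651 and 9 by same-numbered pairs (a replicate block), and 912 to 1936 higher and 14 to 27 lower with each array left out. Of the 12 higher and 4 lower lists, 0 and 0 were left with an estimated correlation, 0 and 0 with fry, and 0 and 0 with an estimated correlation on quantile normalized values. fry, which does not compare a list with other genes, turned the amacrine and horizontal (-0.43 log2 against all genes) and bipolar (-0.40 log2) lists upward.

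Over the named genes and all alternatives, 1821 values kept their direction and side of the threshold, 193 kept the direction but no longer passed, 17 newly passed and 12 changed sign. For the lists these numbers were 439, 56, 6 and 2. The genes that changed sign were, with median-centred arrays, Cdkn1b (-0.014 log2), Gap43 (-0.34), Prox1 (-0.11), Insig1 (-0.0061), Sqle (-0.16), Stard4 (-0.15) and Irf9 (-0.021). With quantile normalized arrays they were Sncg (-0.10) and Gap43 (-0.10), with the mean of a gene's probe sets Tubb3 (0.27), without EGF replicate 1 Slc4a1 (-0.039, and 1.71 at most with another array left out) and without conditioned-medium replicate 2 Hbb (0.26). The cause was not tested beyond the scaling itself. The robust fit was not run for the list test, because camera has no such option. Signal over background limits the dim genes, where a difference is compressed and most open to the scaling.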

Other observations

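The lists in this part were chosen after the results were seen, some of their genes were already among the largest differences, and the tests of explanations were too, except those on the lift of dim probe sets. Adjusted p-values of the 8 added lists are over those 8 alone, so they cannot be set beside those of the 30 fixed lists. As the added lists were picked from these same data, their p-values give no independent support. Annexins and S100 proteins, families of calcium-binding proteins, rose in 12 of 14 tested and fell in 0 (median 1.33 log2 quantile normalized), including Anxa2 (2.08 ± 0.10 SE), Anxa5 (1.80 ± 0.11 SE) and S100a4 (1.46 ± 0.11 SE). Genes of the actin cytoskeleton rose in 13 of 20, among them vinculin, Vcl (1.52 ± 0.11 SE), filamin C, Flnc (1.44 ± 0.26 SE), and Palld (1.26 ± 0.11 SE). That count was 6 without conditioned-medium replicate 2, and Flnc was lost without it or without EGF replicate 2. Both lists were higher in camera (adjusted p = 8.70e-29 and 1.74e-14), each with adjusted p = 0.271 with an estimated correlation on deposited and 0.0479 on quantile normalized values. Mesenchymal markers (9 of 14) and microglia markers (8 of 13) rose beside them. Of 19 targets of the YAP and TEAD transcription factors, 6 rose and 2 fell (camera adjusted p = 0.0105, and adjusted p = 0.815 with an estimated correlation on deposited and 0.337 on quantile normalized values): the receptor tyrosine kinase Axl rose by 1.57 ± 0.12 log2 (SE), and Nt5e (-1.32 ± 0.09 SE) and Dlc1 (-1.07 ± 0.09 SE) fell, of which Dlc1 was lost with the replicate as a block.

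Genes of synaptic transmission fell in 7 of 22 tested and rose in 0 (median -0.69 log2, camera adjusted p = 2.91e-10, and adjusted p = 0.271 with an estimated correlation on deposited and 0.0479 on quantile normalized values), including the vesicle fusion protein Snap25 (-0.95 ± 0.07 SE), synapsin Syn1 (-1.03 ± 0.11 SE) and the vesicular glutamate transporter Slc17a7 (-1.06 ± 0.11 SE). The count was 1 without EGF replicate 1, 0 without EGF replicate 2, 3 without conditioned-medium replicate 1, 1 without conditioned-medium replicate 2 and 0 with the replicate as a block. Microglia markers (8 of 13) and mesenchymal markers (9 of 14) rose in these arrays. Phototransduction genes outside the fixed photoreceptor list fell in 9 of 20 and rose in 0 (camera adjusted p = 4.11e-18, and adjusted p = 0.271 with an estimated correlation on deposited and 0.0479 on quantile normalized values), including Lrit1 (-1.39 ± 0.08 SE), Tulp1 (-1.14 ± 0.09 SE) and the retinoid transporter Abca4 (-1.17 ± 0.14 SE), against 5 without EGF replicate 2 and 5 with the replicate as a block, which lost Abca4. Abca4 was also lost without conditioned-medium replicate 1. Heat shock proteins went both ways: of 11 tested, 3 rose and 1 fell (camera adjusted p = 0.355), with Bag3 at 2.87 log2 and the inducible chaperone Hspa1a at -1.10 ± 0.09 log2 (SE). Hspa1a was lost without EGF replicate 2 and with the replicate as a block, and 1 heat shock gene rose without conditioned-medium replicate 2 and 2 with any other array left out. Ribosomal proteins (16 tested) and ribosome assembly genes (20 tested) gave 0 calls each under all 3 scalings (camera adjusted p = 0.261 and 0.751).

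The deposited values were higher across the array with conditioned medium. Unequal brightness of hybridization or scanning alone is argued against as the whole cause for genes as bright as the hybridization controls: these controls differed by 0.15 log2 and genes of the same brightness by 0.32 log2, an excess of 0.18 log2 that parted the conditions and exceeded the SD of 0.07 log2 within them. Per array the excess was -0.15 and -0.03 log2 with EGF and 0.06 and 0.11 log2 with conditioned medium. The medians of the controls were 9.65 and 9.69 log2 with EGF and 9.87 and 9.66 log2 with conditioned medium, so conditioned-medium replicate 1 carried the difference of these medians. For the dimmest probe sets a higher background remains a candidate explanation, since the 3 trp controls, whose transcript is absent, differed by 0.40 log2 (means of 2.83 and 2.98 with EGF and 3.60 and 3.02 with conditioned medium) and probe sets of the same brightness by 0.39 log2, an excess of 0.014 log2 against an SD of 0.14 log2 within the conditions. A difference in RNA integrity cannot be told apart from the conditions, because the actin 3' to 5' gap differed by -0.58 log2 between them with no overlap. A larger amount of RNA per cell, as an effect of conditioned medium, stays open and untested, and either may have raised the values.

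Photoreceptor genes were lower with conditioned medium. The scaling of the arrays is argued against, since the median of the 17 markers was -0.85 log2 as deposited, where all genes together were higher. The SE of this median, 0.19 log2, takes the markers as independent and does not cover variation between arrays. A single smaller share of photoreceptor-lineage cells would lower all markers by 1 factor if all probe sets responded alike. Over 13 bright markers the SD of the differences was 6.81 times the mean SE of a gene, from -2.41 log2 for Opn1sw to -0.35 log2 for Otx2. That SE covers the replicates of 1 gene and not how probe sets differ in response, so this spread cannot exclude a smaller share. Otx2 may also come from other cells of the retina, and unequal losses of photoreceptor subtypes or a block in maturation could give such a spread. None of these was tested.

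The mesenchymal, microglia, lens and endothelial lists were higher in camera with conditioned medium (adjusted p = 0.629 to 0.646 with an estimated correlation), while the pigment epithelium list was not (camera adjusted p = 0.905). A lift of dim probe sets is argued against for the mesenchymal, microglia and lens lists, whose medians lay above 100%, 100% and 99.13% of 10000 random lists of the same mean levels, and it cannot be told apart for the endothelial list (97.46%, and 97.94% quantile normalized), which lay at the limit. The random lists were drawn gene by gene. If the markers of a list vary together between arrays, these percentiles overstate how unusual it is, most so for the 7 lens markers. Carried-over fibroblasts as the source of Col1a2 and endothelial cells as the source of Ets1 and Flt1 cannot be told apart from an effect of conditioned medium on the retinal cells, because only 2 of the fibroblast genes Col1a1, Col3a1, Dcn and Lum and 0 of the endothelial genes Pecam1, Tie1, Tek and Emcn lie above the limit for dim probe sets. Col1a1 rose (0.60 ± 0.18 SE), though not with any array except EGF replicate 1 left out, as did 9 of 14 mesenchymal markers (3 to 6 with 1 array left out), Col3a1 did not pass under all 3 scalings (0.24 ± 0.32 SE), and the 7 other tested endothelial markers ran from -0.09 log2 for Vwf to 0.72 log2 for Esam. A larger share of microglia remains a candidate explanation for the microglia markers, all 13 of which were above 0 when quantile normalized, and an effect of conditioned medium on the retinal cells was not tested.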
